A study of Gallus gallus with 3 samples.

How the data were processed

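RNA was measured by sequencing in 3 libraries of chick (Gallus gallus) somites, the paired blocks of embryonic mesoderm that give rise to muscle and skeleton. The embryos were at Hamburger-Hamilton stages 14 to 16. One library came from somites injected with an antagomiR against miR-206, a chemically modified antisense oligonucleotide that blocks a muscle microRNA. One came from somites injected with a scrambled antagomiR, and one from somites of the opposite side that received no injection. The labels do not say whether that side belonged to embryos given antagomiR-206, to embryos given the scrambled oligonucleotide or to both, nor how many embryos went into each library. Per the labels' protocols, RNA was taken up in Trizol, libraries were made with an Illumina mRNA-seq kit without barcodes, and each was read from both ends, 50 nt per read, on 1 lane of a Genome Analyzer.

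The deposited table holds whole-number counts for 15878 Ensembl chicken transcript identifiers in each library. Per the file headers, the columns are named by abbreviations. They were assigned by the letters of the sample titles: the initials of non-injected, the start of scrambled, and, for the remaining antagomiR title, the letters of antagomiR. The aligner, the counting tool, the genome build, the annotation release, the use of strand and any filter are not given in the sources used here. Whether 1 count stands for a read or for a read pair is likewise not given. Every cell was a whole number and the column totals differed, so the values were treated as raw counts. No row without an identifier was found, and 115 identifiers had a count of 0 in all 3 libraries.

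The identifiers are not paired with gene names in the deposited table. None of them (0 of 15878) was found in the RefSeq gene table used here, which lists 25635 chicken genes of the GRCg7b assembly by RefSeq accession. No gene name, position or 3' UTR is therefore reported. The 25 gene lists fixed before the data were examined (muscle, sclerotome, neural, blood, signalling and other genes) and the test of miR-206 seed sites could not be run. The rule for single items, fixed at the same time, took the features with the largest ratio, on the log2(CPM + 1) scale, between antagomiR-206 and scrambled libraries. They had to average at least 5 CPM in that pair and differ from both controls by at least 1.5-fold in the same direction. It was applied without its condition of a gene symbol, and the first 2 transcripts in each direction are named by identifier. How far reads were shared between isoforms or paralogs cannot be judged without the counting method. Some identifiers had the same values: ENSGALT00000002186 and ENSGALT00000002187 both had 5.25 CPM in antagomiR-206, 6.52 in scrambled and 6.56 in non-injected libraries. Numbers of transcripts below may therefore not be numbers of separate units.

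Counts were divided by the library total times the TMM factor of edgeR 4.0.16 (R 4.3.3), and are given as CPM, counts scaled to a common library total. The TMM factors were 1.05 for antagomiR-206, 0.995 for scrambled and 0.957 for non-injected. Transcripts with a mean of at least 1 CPM over the 3 libraries were compared, which left 13036. Each ratio is log2(CPM + 1) in one library minus that in the other, so changes of low transcripts are understated. Comparisons were antagomiR-206 against scrambled, antagomiR-206 against non-injected, and scrambled against non-injected, with a threshold of 2-fold. A transcript was said to set a library apart when it differed from both other libraries by at least 2-fold in the same direction while those 2 lay within 1.5-fold of each other.

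There was 1 library per group. No test of a condition was possible and no p-value is given, and a difference between libraries has no replicate check. Exact (Clopper-Pearson) binomial 95% intervals of ratios and Wilson intervals of shares cover counting error only, and reads amplified by PCR are not independent molecules. A count of 0 allows up to 3 counts, which is 0.173 CPM in the antagomiR-206 library, 0.149 CPM in the scrambled library and 0.171 CPM in the non-injected library. As a scale for the observed numbers, 100 sets of 3 libraries were simulated with counting error alone. A further 100 sets had unchanged groups whose pairs varied as the scrambled and non-injected libraries did. In those sets each library's deviation was a ratio between the 2 controls, drawn from transcripts of the same abundance decile, given a random sign and divided by the square root of 2. The form of these simulations was chosen after the data were seen. They assume that all 3 libraries vary alike, and the variation between the 2 controls includes any effect of injecting the scrambled oligonucleotide and any difference between embryos. Their ranges come from redrawing the transcripts of this 1 pair and do not measure how far pairs of unchanged libraries differ.

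The counting of ratios was tested on simulated data with counting error alone, in which 200 transcripts differed by known folds between antagomiR-206 and scrambled libraries. These 200 were drawn from transcripts that averaged at least 5 CPM, so recovery at lower levels was not tested. Among 13016 transcripts, 98% of the 50 changed by 3-fold and 100% of those changed by 4-fold or 8-fold were recovered, with 0 unchanged transcripts called. Of the 50 changed by 1.5-fold, which lies under the 2-fold threshold, 0% were recovered. This test checks the arithmetic and gives no rate of false calls: with the variation between the 2 controls, 101 unchanged transcripts on average were called in the same pair. Alternatives were a smaller and a larger pseudocount, 2 other filters on low values, DESeq2 1.42.0 size factors, upper quartile scaling, a 3-fold threshold, the non-injected library as the control and, added after the data were seen, scaling by total counts alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.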

Results

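Transcript abundance was compared in 3 libraries of chick somites from stages 14 to 16: somites injected with an antagonist of miR-206, somites injected with a scrambled oligonucleotide of the same class, and non-injected somites of the opposite side. The antagomiR-206 library held 16496794 counts, the scrambled library 20176114 and the non-injected library 18332350. Of the 15878 transcripts listed, 15207 had at least 1 count in the antagomiR-206 library, 15373 in the scrambled library and 15384 in the non-injected library. The median count per transcript was 306.5, 354 and 307 in the same order. Each group was represented by 1 library, so the differences below are between libraries and have no replicate check.

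The non-injected library was the most concentrated on its abundant transcripts and the antagomiR-206 library the least. The 100 most abundant transcripts of each library took 23.6% of the non-injected counts (95% Wilson interval 23.58 to 23.62), 21.1% of the scrambled counts (21.09 to 21.12) and 19.3% of the antagomiR-206 counts (19.24 to 19.28). The single most abundant transcript took 1.39%, 1.20% and 1.07% in that order. These differences exceeded counting error by far, but whether they exceed the variation between libraries of one group cannot be judged from 1 library each.

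The first comparison asked which transcripts differed in the presence of the miR-206 antagonist, with the scrambled oligonucleotide as the injected control. Of 13036 transcripts, 48 were at least 2-fold higher and 87 at least 2-fold lower in the antagomiR-206 library, 1.04% in all. The exact 95% counting intervals of all 135 excluded equal levels, as did those of 54.0% of all transcripts compared. With 1 CPM added, a 2-fold call already needs a gap beyond counting error, so this adds no support. It also held for all 390 calls against non-injected and all 102 between the 2 controls. In simulated libraries with counting error alone, 0.01 transcripts on average reached 2-fold. In simulated unchanged libraries that varied as the 2 controls did, 101 did so on average, with a range of 72 to 122 over 100 draws. This mean restates the 102 of the 1 control pair it was drawn from. The range does not cover differences between pairs of libraries. The SD of the log2 ratio over transcripts was 0.34, against 0.12 from counting error alone and 0.34 (0.33 to 0.35) in the unchanged libraries with control variation. At a lower threshold of 1.5-fold, 338 transcripts were higher and 551 lower.

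Among transcripts that averaged at least 5 CPM in this pair, 106 were at least 1.5-fold higher in the antagomiR-206 library than in both controls and 268 were at least 1.5-fold lower than in both. Among those 106, ranked on the log2(CPM + 1) scale, ENSGALT00000036887 had the highest ratio to the scrambled library, at 49.1 CPM against 13.9 CPM, a 3.52-fold difference in plain CPM (exact 95% interval 3.07 to 4.04). It stood at 26.0 CPM in the non-injected library, so the difference from that control was 1.89-fold (1.68 to 2.12). ENSGALT00000043708 was among the abundant transcripts, at 1441 CPM in the antagomiR-206 library, 455 CPM in the scrambled library and 708 CPM in the non-injected library. It was 3.17-fold higher than in the scrambled library (3.10 to 3.25) and 2.03-fold higher than in the non-injected library (1.99 to 2.08). For both transcripts the scrambled library lay below the non-injected one.

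Among the 268 lower transcripts, the largest differences on the same scale were of transcripts close to absent from the antagomiR-206 library. ENSGALT00000043628 had 11 counts there, 740 in the scrambled library and 512 in the non-injected library. Its CPM was 58.0-fold lower than in the scrambled library (exact 95% interval 32.2 to 117) and 46.0-fold lower than in the non-injected library (25.5 to 92.7). ENSGALT00000024434 had 10 counts against 387 in the scrambled library and 999 in the non-injected library, 33.4-fold lower (18.0 to 70.2) and 98.7-fold lower (53.4 to 206.4). On the log2(CPM + 1) scale the ratios to the scrambled library were -4.53 and -3.68. These depended on the pseudocount: with 0.1 CPM they were -5.65 and -4.84, and with 5 CPM -2.89 and -2.12.

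**Figure D1:**
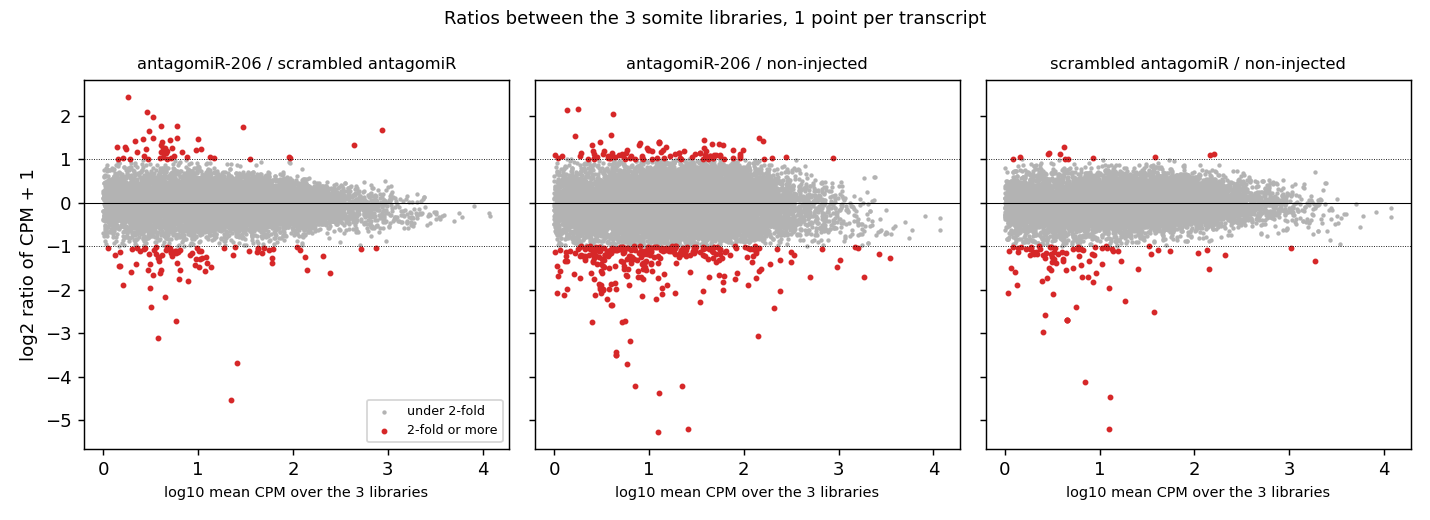
Log2 ratio of CPM + 1 (vertical axis) against the log10 mean CPM over the 3 libraries (horizontal axis) for 13036 transcripts, 1 panel per pair of libraries; red points are at least 2-fold apart (dotted lines) and there are no replicates. The antagomiR-206 and non-injected libraries have 390 red points, against 135 and 102 in the other pairs.

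The second comparison set the antagomiR-206 library against the library of the side that was not injected; the labels do not tell which of the injected embryos that side came from, or how many were pooled. Here 96 transcripts were at least 2-fold higher and 294 at least 2-fold lower, 2.99% of those compared and 2.9 times the number found against the scrambled control. The simulated unchanged libraries gave 104 on average, with a range of 78 to 135 from redrawing the 1 control pair. The SD of the log2 ratio was 0.49, and 20.5% of transcripts differed by at least 1.5-fold. The split of higher and lower transcripts depended on the scaling. With total counts in place of TMM the median log2 ratio of all transcripts moved from -0.01 to 0.12, and of the 397 transcripts past 2-fold 51.9% were higher and 191 lower, against 24.6% higher with TMM.

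The third comparison, scrambled against non-injected, gives the difference between libraries of somites not injected with the miR-206 antagonist. The non-injected side may still have come from embryos given it on the other side. In it 12 transcripts were at least 2-fold higher in the scrambled library and 90 at least 2-fold lower, 102 in all. The SD of the log2 ratio was 0.34, the same to 2 decimals as between the antagomiR-206 and scrambled libraries. At 1.5-fold, 897 transcripts differed here and 889 between the antagomiR-206 and scrambled libraries. The number past 2-fold in the main comparison, 135, was 1.3 times that between the 2 control libraries. This order did not hold at every setting: the numbers were 28 and 30 with a pseudocount of 5 CPM, and 22 and 22 past 3-fold.

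Transcripts that differed from both controls were sought next. Of the transcripts at least 2-fold lower in the antagomiR-206 library, 57 were so against both controls, as were 10 of those higher. Independent lists of these sizes would share 1.96 and 0.35. Both comparisons use the same antagomiR-206 library, and unchanged simulated libraries shared 13.7 lower and 13.5 higher transcripts. Those came from simulated lists of 101 and 104 transcripts on average, both directions together, so they are not values for lists of the observed sizes. The random sign in the simulation also made both directions equally likely, so they are no scale for a single direction. The ratios to the 2 controls correlated across transcripts at r = 0.71, with a covariance of 0.117. The simulated values were 0.50 and 0.058, and transcripts are not independent replicates. Such values of r and covariance are fixed by the SDs of the pairs of libraries. They are therefore no separate evidence of a shared difference from both controls. The antagomiR-206 library cannot be split, so part of any excess over independent lists may come from it.

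With the further condition that the 2 other libraries lay within 1.5-fold of each other, 46 transcripts set the antagomiR-206 library apart, 8 higher and 38 lower. The same number, 46, set the non-injected library apart, 42 higher and 4 lower. The scrambled library was set apart by 7, of which 1 was higher and 6 were lower. Simulated unchanged libraries gave 25.1, 26.3 and 25.2 on average, with ranges of 13 to 38, 11 to 44 and 15 to 38. For lower transcripts alone the simulated means were 12.7 (5 to 22), 12.9 (4 to 23) and 12.7 (5 to 23), against 38, 4 and 6 observed. The random sign made both directions equally likely in the simulation, while the control pair had 12 higher and 90 lower. These means are therefore no scale for a single direction, and no excess can be read from them. In both directions together, the antagomiR-206 library was therefore not set apart by more transcripts than the non-injected library. With other pseudocounts the order of these 2 libraries went either way. With total count scaling 16 higher and 29 lower transcripts set the antagomiR-206 library apart.

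**Figure D2:**
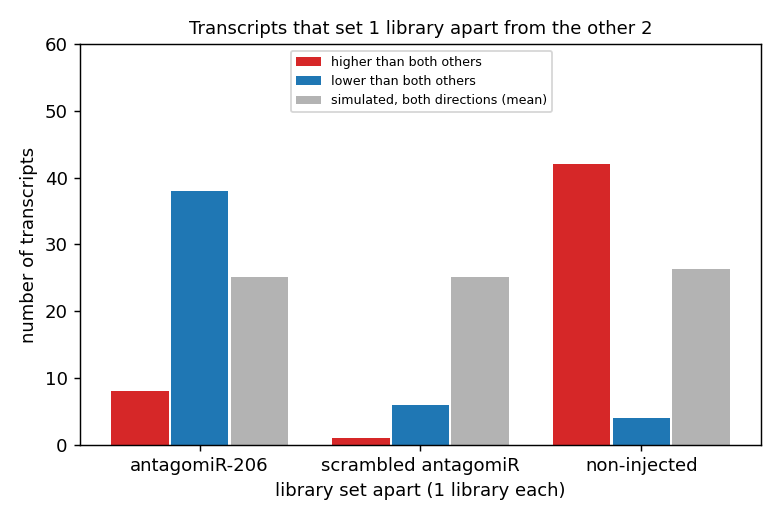
Number of transcripts (vertical axis) that differ by at least 2-fold from both other libraries, which lie within 1.5-fold of each other, for each library (horizontal axis, 1 library each); grey bars are the mean of 100 simulated sets of unchanged libraries, both directions together. The antagomiR-206 library has 38 lower and 8 higher transcripts, and the non-injected library 42 higher and 4 lower.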

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

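Of 49 recomputed counts of transcripts, both directions together, 25 stayed within 1.5 times the reported value and 24 moved further. DESeq2 size factors, upper quartile scaling, total count scaling (added after the data were seen) and no filter on low values left every such total within that range. The directions were less stable: total count scaling raised the higher share from 24.6% to 51.9% of those past 2-fold against non-injected, and from 17.4% to 35.6% of those that set the antagomiR-206 library apart. In the order antagomiR-206 against scrambled, antagomiR-206 against non-injected, and scrambled against non-injected, the counts past 2-fold (135, 390 and 102 as reported) were 310, 695 and 252 with a pseudocount of 0.1 CPM. They were 28, 128 and 30 with a pseudocount of 5 CPM, and 22, 71 and 22 past 3-fold. A mean of at least 5 CPM gave 74 in the first and 46 in the third. With the non-injected library as the control, the main count was 390. The numbers that set the antagomiR-206, scrambled and non-injected libraries apart (46, 7 and 46 as reported) were 120, 35 and 105 with 0.1 CPM, 10, 0 and 20 with 5 CPM, 29, 2 and 25 with a mean of at least 5 CPM, and 6, 0 and 13 past 3-fold. A larger threshold lowers both kinds of count by construction, and a larger pseudocount lowers those past 2-fold. The set-apart counts also need the 2 other libraries within 1.5-fold, which a larger pseudocount makes easier to meet. The equality of the antagomiR-206 and non-injected numbers thus rests on the setting. The antagomiR-206 number was higher with 0.1 CPM, with the 5 CPM filter and with total count scaling (45 against 41). The non-injected number was higher with 5 CPM, past 3-fold and with no filter on low values (52 against 46). It was also higher with DESeq2 size factors and with upper quartile scaling (46 against 45 in each). Of 28 recomputed ratios of the 4 named transcripts, 22 lay within counting error of the reported value and no ratio changed sign. The 2 filters on low values cannot alter a ratio, so their part of these ratios was the same by construction. No pseudocount can reverse a sign, and the scalings shift all transcripts alike, so the unchanged signs show no stability. No replicate could be left out and no paired analysis was possible because each group had 1 library. Other settings for the gene lists and the seed sites were not run, since the identifiers have no names or sequences here.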

Other observations

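The tests of the abundance trend, of mixed material, of separate effects and of counting error were written before their results were seen, although the patterns themselves had been noticed first. The counts of transcripts near 0 in single libraries, the simulated libraries and the test against control variation were chosen after the data were seen. Without gene names, explanations by tissue, cell type or microRNA target were not tested.

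At least 30 counts in the non-injected library and at most 3 in each injected library were found for 4 transcripts, and 0 transcripts had the reverse. The highest of these had 660 counts in the non-injected library, 1 in the scrambled library and 0 in the antagomiR-206 library. Against the limit of 3 counts in the antagomiR-206 library, it was at least 217-fold higher in the non-injected library. In the antagomiR-206 library, 3 transcripts had at most 3 counts while both other libraries had at least 30, and the scrambled library had 0 such transcripts in either direction.

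Taken over all transcripts, the scrambled library was closer to each of the other 2 than they were to each other. The SD of the log2 ratio was 0.34 in both pairs with the scrambled library and 0.49 between the other 2. This does not place each transcript in between. Of those at least 1.5-fold apart in both pairs with the scrambled library, 91 had a scrambled level outside the other 2 and 59 between them. Across transcripts, the ratio of antagomiR-206 to scrambled and the ratio of scrambled to non-injected correlated at r = 0.04, where simulated libraries that vary alike gave -0.50, with a range of -0.53 to -0.47. Equal variation of the 3 libraries was not tested, so this difference does not by itself show an intermediate library. Each of these correlations is fixed by the SDs of the pairs of libraries, so it restates those SDs and is no further observation. An abundance-dependent scaling error is argued against, since removing the running median by abundance left the correlation at 0.03 (0.0324). Mixing of material with counting error alone is argued against. The scrambled level lay at least 1.5-fold outside the other 2 for 91 transcripts. Simulated libraries with counting error alone gave 1.24 on average and at most 4. This count was not part of the test written beforehand. Mixing together with further variation of the scrambled library itself remains open. Of 33 transcripts at least 4-fold apart between the antagomiR-206 and non-injected libraries, 6 had a scrambled level outside the range those 2 span (18.2%, exact 95% interval 6.98 to 35.5). The rule written beforehand used the share alone, and this share was past its limit against mixing. The interval reaches below that limit, but use of the interval was not part of the written rule. Separate effects of injection and of the antagonist, as the design would allow, also remain open, and no test here decides on them. In the same direction in both steps, 59 transcripts differed by at least 1.5-fold (1.84 times the 32.1 of independent lists, which leave out the scrambled library shared by the steps, against 4.94 on average and 0 to 10 in unchanged simulated libraries, which leave out real effects), and 91 did so in opposite directions, against 29.1 and 249. The stage, level and makeup of the dissected somites could not be examined, and any of these may differ between libraries.

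In the antagomiR-206 library, 2 transcripts were at least 8-fold below both other libraries on the log2(CPM + 1) scale, and in each of the other libraries 0 were. Counting error at the depth of these libraries is argued against: it gave 0 such transcripts on average over 100 simulated sets. Variation of the size seen between the 2 control libraries gave 0.74 on average and up to 4 in one set. Those drops came from ratios of that single pair, which ran from -5.20 to 1.27 in log2 and were given a random sign. The simulated levels were also not held above 0 CPM. The simulation therefore cannot decide whether such variation accounts for the 2 transcripts. With 1 library per group, it cannot be told apart from an effect of the antagonist. A biological effect was not tested beyond this.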
